A study of Mus musculus with 16 samples.

How the data were processed

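Total RNA from kidney cortex of 3-month-old mice was extracted with Trizol, labelled with biotin and hybridized to Affymetrix mouse arrays, per the labels' protocols. The deposited log2 values were made by robust multi-array averaging (RMA) in Affymetrix Expression Console 1.4, per the submitters' processing notes. The table holds 41345 probe sets for 16 arrays, 4 in each of 4 genotype groups taken from the labels, and 0 of its columns of values were left unused. The annotation lists 25335 of the probe sets, 23521 with 1 gene symbol and 1814 with several, which were left out together with the 16010 that it does not list. For the 1082 genes with more than 1 probe set the one of highest mean was used, which left 22180 genes. Gene names and neighbours came from a RefSeq table of the GRCm38.p6 assembly, in which 23328 of the probe sets with 1 symbol were found by Entrez ID. The array's own build is not named, so no coordinates are given. No expression filter was applied. The lower quartile of an array lay between 3.60 and 3.72. Genes whose mean in a compared group was below 3.72 may be at background there and are given as levels, with no fold, a choice made after values were seen.

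The descriptions give each array a number, with 2 numbers per group, and a letter, L or R, whose meaning is not given. The numbers may mark animals; a group then holds 2 animals, not 4, and the p-values measure partly technical spread. The number of arrays limits the precision. Wild-type, Vhl mutant and Pbrm1 mutant replicates 1 and 2 share a number, as do 3 and 4; double mutant replicates 1 to 3 share one and replicate 4 has its own. Linear models were fitted with limma 3.58.1 in R 4.3.3, with the 4 groups as fixed effects and the number as a random block (estimated correlation 0.0838). Moderated tests used a prior variance that follows mean expression (prior degrees of freedom 7.73, residual 12). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes come from this fit, which weights double mutant replicate 4 more, so they differ slightly from differences of group means. The 7 comparisons were each mutant group against wild type, the mutant groups against each other, and the interaction, which is the double mutant effect minus the sum of the single effects.

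Fixed lists of genes (32 lists, 707 genes, 636 tested), written before the data were examined like the model, the comparisons and the rule for named genes, were tested with limma's camera on the moderated statistics. The inter-gene correlation was preset at 0.01, and p-values were adjusted over all 224 tests. Each list was tested again with its correlation estimated from the residuals. Counts adjusted over the list alone use the members' p-values only. Some lists share members, hypoxia and glycolysis among them. Named genes were, per comparison, the 6 called genes with the largest rise and the 6 with the largest fall whose groups did not overlap, up to 4 called members of each called list, and both deleted genes; no overlap was required for the interaction. The strain-variable genes given singly, the most abundant macrophage and adipose markers and the order of the Serpina genes were chosen after values were seen.

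In simulated data for Vhl mutants against wild type, with 22180 genes, 76% of planted changes of 1.5-fold were called, 98% of 2-fold and 100% of 4-fold. Of calls, 7.88% were not planted. A list shifted by 0.5 for Pbrm1 mutants against wild type had adjusted p = 7.7e-44. With none planted, double mutants against wild type gave 0 genes and 0 lists. Real arrays of these groups split evenly gave up to 7 lists, and those of double and Vhl mutants up to 14. A simulated correlation of 0.1 within a number was estimated as 0.0359, so the correlation estimated from the arrays may be too low. Overlaps between comparisons sharing wild-type arrays were set against 20 simulations of unchanged groups and split controls. Alternatives were no block, arrays averaged per number, the replicate number as a block, merged or moved double mutant replicate 3, a filter on dim genes, the mean of a gene's probe sets, centring, quantile normalization, array weights, no trend, only the groups compared, a 1.5-fold minimum, and leaving out each array or each number. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures.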

Results

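RNA from the kidney cortex of 3-month-old mice was measured on 16 Affymetrix arrays, 4 for each of 4 genotypes. The groups were wild-type mice, mice with loxP-flanked (floxed) Vhl and Ksp-Cre, mice with floxed Pbrm1 and Ksp-Cre, and double mutants with both floxed genes and Ksp-Cre. Ksp-Cre expresses the Cre recombinase from the promoter of Cdh16, a cadherin of kidney tubule epithelium. Vhl encodes the ubiquitin ligase subunit that marks hypoxia-inducible factors for degradation, and Pbrm1 encodes a subunit of the SWI/SNF chromatin remodeler PBAF. Both are tumor suppressor genes of clear cell renal cell carcinoma (ccRCC), and the stated purpose was to find early transcriptional events that could matter for the formation of that tumor. The deposited values are log2 expression after robust multi-array averaging, and the median of an array lay between 5.18 and 5.27. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.11 between the single-mutant and wild-type groups and 0.16 for the interaction. The labels give the wild-type strain as C57BL/6 and that of all mutants as a mix of that strain with others, so each comparison with wild type also compares strains. The labels do not say that the 4 arrays of a group came from 4 animals, so p-values measure the spread between these arrays, which may be technical. The description numbers of the Vhl mutant arrays lie above those of all other groups, and a batch behind this, if there was one, could not be told apart from the Vhl mutant genotype. The first principal component held 24.5% of the variance and the second 15.3%.

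**Figure D1:**
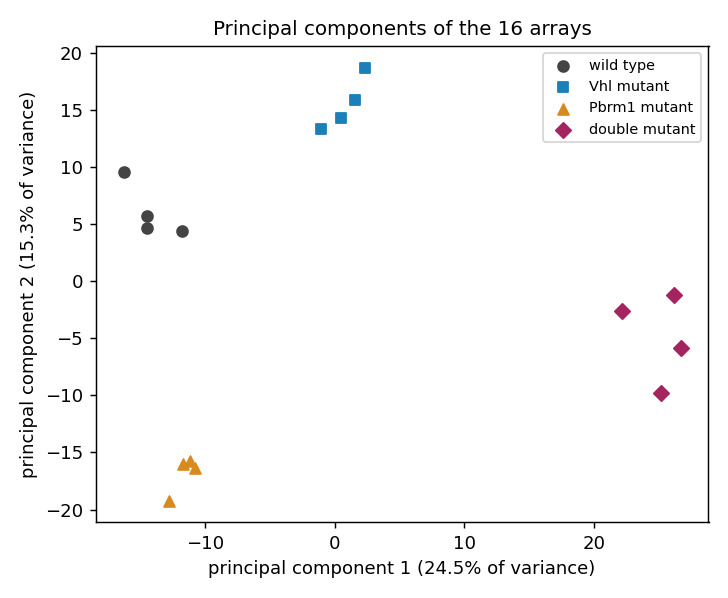
Scores of the 16 arrays on principal components 1 and 2 over all tested genes (x and y axes, in log2 units), with 24.5% and 15.3% of the variance; each point is 1 array and shapes and colours mark the genotype. The double mutants lie between 22.2 and 26.7 on component 1 and the other arrays between -16.3 and 2.36, while the Pbrm1 mutants lie between -19.2 and -15.8 on component 2.

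The probe sets of the deleted genes did not separate the genotypes. Vhl measured 6.34 ± 0.15 (mean ± SD of log2 values, n = 4) in wild-type kidneys, 6.28 ± 0.02 in Vhl mutants, 6.26 ± 0.04 in Pbrm1 mutants and 6.22 ± 0.20 in double mutants. Pbrm1 measured 8.19 ± 0.05, 8.13 ± 0.14, 8.19 ± 0.04 and 8.13 ± 0.08 in the same order. In double mutants against wild type the log2 fold change was -0.12 ± 0.10 SE for Vhl (limma adjusted p = 0.55) and -0.07 ± 0.07 SE for Pbrm1 (adjusted p = 0.61), and neither gene passed in any of the 7 comparisons. Each gene has 1 probe set on the array, which may cover exons that the deletion leaves in place and also measures cells without Cre, so these values check nothing about the labels.

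The first comparison asked what loss of Vhl alone did to the cortex. Genes induced by hypoxia-inducible factors rose: Egln3, a prolyl hydroxylase that marks these factors for degradation and is itself one of their targets, rose 4.56-fold (log2 fold change 2.19 ± 0.14 SE, adjusted p = 1.4e-08, n = 4 arrays per group), from 6.47 ± 0.26 to 8.66 ± 0.11 (mean ± SD, log2). Slc16a3, the lactate exporter MCT4, rose 3.03-fold (log2 fold change 1.60 ± 0.12 SE, adjusted p = 1.3e-07), Hk2, a hexokinase, 2.67-fold, and Adm, the vasodilator adrenomedullin, 2.20-fold. Of the hypoxia-inducible factor targets, 15 of 32 rose, 17 up adjusted over the list alone (adjusted p = 5.0e-30, camera, as for all lists). Of the glycolysis genes, 10 of 15 rose, 12 up adjusted over the list alone (adjusted p = 1.3e-47), among them the phosphofructokinases Pfkp (log2 fold change 1.21 ± 0.07 SE) and Pfkl (1.0 ± 0.08 SE).

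Markers of tubular injury and inflammation also rose in Vhl mutants. Lcn2, the iron-scavenging lipocalin released by injured tubules, rose 3.32-fold (log2 fold change 1.73 ± 0.17 SE, adjusted p = 6.5e-06); of the tubular injury genes, 12 of 20 rose, 14 up adjusted over the list alone (adjusted p = 7.7e-22). Called members included the adhesion molecule Vcam1 (log2 fold change 0.86 ± 0.13 SE) and the cell cycle inhibitor Cdkn1a (0.82 ± 0.12 SE). Of the STAT3 targets and acute phase genes, 8 of 22 rose, 11 up adjusted over the list alone (adjusted p = 1.2e-19). Called genes included the oncostatin M receptor Osmr (log2 fold change 0.97 ± 0.10 SE) and the copper carrier Cp (0.82 ± 0.10 SE). Havcr1, the injury marker KIM-1, rose 3.85-fold (log2 fold change 1.95 ± 0.47 SE, adjusted p = 0.022), a call that ended without wild-type replicate 1 or Vhl mutant replicates 1 or 3 (adjusted p from 0.055 to 0.078). Among macrophage markers, 16 of 19 rose, 18 up adjusted over the list alone (adjusted p = 5.6e-37, 5.3e-08 with an estimated correlation). These included the lysosomal protease Ctss (log2 fold change 0.97 ± 0.10 SE), Cd53 (0.71 ± 0.10 SE) and the fractalkine receptor Cx3cr1 (0.68 ± 0.09 SE). Of the lymphocyte markers, 3 of 17 rose, 3 up adjusted over the list alone (adjusted p = 2.9e-06), one being Jchain, which joins antibody units (log2 fold change 1.07 ± 0.22 SE). Of the interferon response genes, 7 of 20 rose, 11 up adjusted over the list alone (adjusted p = 5.4e-12). Of the extracellular matrix genes, 11 of 26 rose, 19 up and 1 down adjusted over the list alone (adjusted p = 1.3e-17, and adjusted p = 0.017 with an estimated correlation). Called members included Tgfbi (log2 fold change 0.99 ± 0.14 SE) and fibronectin, Fn1 (0.80 ± 0.12 SE). Endothelial markers rose as a list (7 of 17 rose, 14 up adjusted over the list alone, adjusted p = 9.0e-17), including Cdh5, vascular endothelial cadherin (log2 fold change 0.58 ± 0.09 SE), and Emcn (0.57 ± 0.07 SE). Of the cell cycle genes, 2 of 27 rose, 8 up adjusted over the list alone (adjusted p = 1.4e-07). Called genes included the proliferation marker Mki67 (log2 fold change 0.87 ± 0.15 SE). The adipose list median (log2), a measure of fat, lay between 0.06 and 0.49 in Vhl mutants and between -0.07 and 0.05 in wild type.

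Markers of several distal nephron cells fell in Vhl mutants. Of the intercalated cell genes, 8 of 18 fell, 1 up and 11 down adjusted over the list alone (adjusted p = 1.6e-16). These included the anion exchanger Slc26a4 (log2 fold change -0.86 ± 0.10 SE, adjusted p = 4.7e-05), the ammonia channel Rhcg (log2 fold change -0.74 ± 0.08 SE) and the proton pump subunit Atp6v1b1 (-0.62 ± 0.08 SE). Of the thick ascending limb genes, 6 of 16 fell, 8 down adjusted over the list alone (adjusted p = 5.9e-08, and adjusted p = 0.011 with an estimated correlation). Called members included Bsnd, a chloride channel subunit (log2 fold change -0.66 ± 0.09 SE), and Wfdc15b (-0.67 ± 0.10 SE). In the red blood cell list, which was lower, 1 of 3 fell, 2 down adjusted over the list alone (adjusted p = 0.013). In the list of Pbrm1 neighbours, 3 of 31 fell, 6 down adjusted over the list alone (adjusted p = 0.0038). Of its members, 24 lie on chromosome 14 with Pbrm1 and 7 on chromosome 9 (GRCm38.p6), and for those 24 alone, of which 1 fell, the list call ended (adjusted p = 0.059). The next lists of this paragraph passed with the preset correlation only. In the distal convoluted tubule list, which was lower, 4 of 15 fell, 1 up and 7 down adjusted over the list alone (adjusted p = 7.6e-04, and adjusted p = 0.21 with an estimated correlation). In the smooth muscle and renin cell list, which was higher, 2 of 9 rose and 1 fell, 4 up and 1 down adjusted over the list alone (adjusted p = 4.1e-05, and adjusted p = 0.051 with an estimated correlation). In the SWI/SNF subunit list, which was lower, 1 of 23 fell, 1 down adjusted over the list alone (adjusted p = 0.0038, and adjusted p = 0.078 with an estimated correlation). In the sex-dependent kidney gene list, which was lower, 1 of 13 rose and 2 fell, 2 up and 4 down adjusted over the list alone (adjusted p = 0.036, and adjusted p = 0.069 with an estimated correlation). The sex-dependent kidney gene call ended without wild-type replicates 1, 2 or 3 or Vhl mutant replicate 3 (adjusted p from 0.063 to 0.087).

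Of 22180 genes, 453 rose and 398 fell in Vhl mutants (limma), and 262 of these 851 changed at least 1.5-fold. The largest falls among genes whose groups did not overlap in any array were Hspa1a, the inducible heat shock protein (fell 5.13-fold; log2 fold change -2.36 ± 0.48 SE, adjusted p = 0.0068), the fatty acid hydroxylase Cyp4a12a (5.06-fold), the carboxylesterase Ces1g (4.47-fold), Tldc2 (2.90-fold), the stress gene Gadd45g (2.51-fold) and Lonrf1 (2.25-fold). The largest rises also held the immunoglobulin segment Igkv9-120 (log2 mean 3.64 in wild type and 6.64 in Vhl mutants), the fatty acid hydroxylase Cyp4a14 (3.45-fold), the small nucleolar RNA Snord13 (5.96-fold) and Gm3893 (3.43-fold). Igkv9-120, Cyp4a12a and Cyp4a14 belong to families of near-identical genes whose probe sets may not tell members apart. The call of Snord13 ended without Vhl mutant replicate 3 (adjusted p = 0.058) and that of Gm3893 without wild-type replicates 3 or 4 or Vhl mutant replicate 1 (adjusted p from 0.067 to 0.071). The count was 537 without wild-type replicate 1, 559 without wild-type replicate 2, 541 without Vhl mutant replicate 3, 275 without wild-type replicates 1 and 2 together, 246 with arrays averaged per description number and 564 without the 3 arrays of raised adipose markers. Centring each array on its median gave 355 higher and 622 lower genes, 36.3% higher against 53.2%. The balance moved the other way, to 188 and 58 (76.4%) for averaged arrays and 186 and 76 (71.0%) for the 1.5-fold minimum.

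Loss of Pbrm1 alone was tested against the same wild-type arrays. Azgp1, a secreted zinc-binding glycoprotein, fell 20.3-fold (log2 fold change -4.34 ± 0.18 SE, adjusted p = 7.8e-12, n = 4 arrays per group), from 9.35 ± 0.25 to 5.0 ± 0.41 (mean ± SD, log2). Cpn1, the catalytic chain of carboxypeptidase N, fell 13.5-fold (log2 fold change -3.75 ± 0.17 SE, adjusted p = 3.4e-11). Angptl7, a secreted angiopoietin-like protein, rose 12.2-fold (log2 fold change 3.61 ± 0.21 SE, adjusted p = 1.3e-09), and Akr1c18, a hydroxysteroid dehydrogenase that inactivates progesterone, rose 4.86-fold (log2 fold change 2.28 ± 0.30 SE, adjusted p = 9.2e-05). Falls followed for the cytochrome P450 Cyp2c23 (4.45-fold), 2610507I01Rik (4.25-fold), the phospholyase Etnppl (3.68-fold) and 3110045C21Rik (3.29-fold), and rises for Eddm3b (5.14-fold), Igkv9-120 (to a log2 mean of 5.94), the aldehyde dehydrogenase Aldh1a7 (4.82-fold) and the collagen chain Col6a6 (4.41-fold).

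With an estimated correlation, 4 lists passed in Pbrm1 mutants. Of the interferon response genes, 3 of 20 fell, 6 down adjusted over the list alone (adjusted p = 3.3e-05, and adjusted p = 0.022 with an estimated correlation). Called genes included Oasl2 (log2 fold change -0.57 ± 0.12 SE, adjusted p = 0.0087) and Usp18, which removes the ubiquitin-like protein ISG15 from its targets (log2 fold change -0.54 ± 0.11 SE). Of the NRF2 targets, 2 of 16 fell, 3 down adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.035 with an estimated correlation), one being Osgin1 (log2 fold change -0.89 ± 0.13 SE). In the list of Pbrm1 neighbours, 4 of 31 fell, 5 down adjusted over the list alone (adjusted p = 0.002 and 0.0069 with an estimated correlation). Of the 24 on chromosome 14, 3 fell, 3 adjusted over the list alone (adjusted p = 0.012 and 0.016 respectively). They include the troponin Tnnc1 (log2 fold change -1.06 ± 0.15 SE), lower in Vhl mutants too (-0.88 ± 0.15 SE). Of the genes known to differ between inbred strains, 4 of 19 rose and 1 fell, 6 up and 3 down adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.0093 with an estimated correlation). Gbp2b rose to a log2 mean of 4.82 from 3.39. The histocompatibility gene H2-Q10 (log2 fold change 1.3 ± 0.19 SE) and Wdfy1 (0.94 ± 0.08 SE) rose. The insulin-degrading enzyme Ide (log2 fold change -0.42 ± 0.05 SE) fell. In the cholesterol synthesis list, which was lower, 1 of 16 rose and 2 fell, 2 up and 4 down adjusted over the list alone (adjusted p = 0.0052, and adjusted p = 0.16 with an estimated correlation). The synthase Hmgcs1 fell 2.06-fold (log2 fold change -1.04 ± 0.07 SE, adjusted p = 3.1e-08) and the sterol desaturase Sc5d 1.84-fold, while the lanosterol demethylase Cyp51 rose 1.33-fold. The next lists of this paragraph passed with the preset correlation only. In the extracellular matrix list, which was lower, 3 of 26 fell, 5 down adjusted over the list alone (adjusted p = 1.3e-04, and adjusted p = 0.32 with an estimated correlation). The fibronectin gene Fn1 (log2 fold change -0.87 ± 0.12 SE) fell. In the endothelial list, which was lower, 2 of 17 fell, 5 down adjusted over the list alone (adjusted p = 6.0e-04, and adjusted p = 0.063 with an estimated correlation). In the smooth muscle and renin cell list, which was lower, 1 of 9 fell, 2 down adjusted over the list alone (adjusted p = 0.0064, and adjusted p = 0.21 with an estimated correlation). In the distal convoluted tubule list, which was lower, 4 of 15 fell, 1 up and 4 down adjusted over the list alone (adjusted p = 6.8e-04, and adjusted p = 0.2 with an estimated correlation). The sodium-chloride cotransporter Slc12a3 (log2 fold change -0.35 ± 0.06 SE) and its regulator Klhl3 (-0.42 ± 0.08 SE) fell. In the intercalated cell list, which was lower, 2 of 18 fell, 1 up and 4 down adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.23 with an estimated correlation). In the tubular injury list, which was lower, 1 of 20 fell, 1 up and 4 down adjusted over the list alone (adjusted p = 0.0062, and adjusted p = 0.22 with an estimated correlation). In the sex-dependent kidney gene list, which was higher, 4 of 13 rose and 1 fell, 4 up and 1 down adjusted over the list alone (adjusted p = 0.026, and adjusted p = 0.054 with an estimated correlation). The sex-dependent kidney gene call ended without wild-type replicate 4 (adjusted p = 0.074).

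In Pbrm1 mutants 352 genes rose and 543 fell, 895 in all, of which 235 changed at least 1.5-fold. The count was 318 without Pbrm1 mutant replicates 3 and 4, 424 without wild-type replicates 1 and 2, 577 without wild-type replicates 3 and 4, 274 with arrays averaged per description number and 501 without the 3 arrays of raised adipose markers, of which Pbrm1 mutant replicate 3 had the highest adipose list median, 0.65.

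Loss of both genes was then compared with wild type. Havcr1 rose 26.5-fold (log2 fold change 4.73 ± 0.48 SE, adjusted p = 7.3e-07, n = 4 arrays per group), from 4.34 ± 0.45 to 9.04 ± 0.45 (mean ± SD, log2), and Lcn2 rose 8.73-fold (log2 fold change 3.13 ± 0.17 SE, adjusted p = 3.3e-10). The fibrinogen chains Fgg and Fga, acute phase proteins, rose 15.6-fold (log2 fold change 3.96 ± 0.20 SE, adjusted p = 1.1e-10) and 4.87-fold (log2 fold change 2.28 ± 0.13 SE, adjusted p = 3.3e-10). Of the STAT3 targets and acute phase genes, 18 of 22 rose, 20 up adjusted over the list alone (adjusted p = 1.6e-50). Of the tubular injury genes, 18 of 20 rose, 18 up adjusted over the list alone (adjusted p = 6.3e-38). These included Cdkn1a (log2 fold change 1.61 ± 0.12 SE), Krt19, a keratin (1.52 ± 0.15 SE), and Vcam1 (1.46 ± 0.13 SE). Of the hypoxia-inducible factor targets, 19 of 32 rose and 1 fell, 19 up and 1 down adjusted over the list alone (adjusted p = 5.5e-24). Called members included Egln3 (up 5.33-fold, log2 fold change 2.41 ± 0.14 SE, adjusted p = 4.7e-10). The member that fell was Plin2, a coat protein of lipid droplets, by 2.41-fold (log2 fold change -1.27 ± 0.08 SE, adjusted p = 8.5e-10). Of the glycolysis genes, 12 of 15 rose, 13 up adjusted over the list alone (adjusted p = 3.2e-42). Called genes included Pfkp (up 3.35-fold) and Slc16a3 (up 3.82-fold).

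Genes of the mitochondrial respiratory chain and of specialised tubule cells were lower in double mutants than in wild type. Of the oxidative phosphorylation genes, 32 of 66 fell, 2 up and 38 down adjusted over the list alone (list median log2 fold change -0.17, adjusted p = 2.6e-14, and adjusted p = 0.0041 with an estimated correlation). The complex I subunits Ndufc2 (log2 fold change -0.83 ± 0.07 SE, adjusted p = 6.0e-08) and Ndufa2 (log2 fold change -0.48 ± 0.07 SE) and the cytochrome oxidase subunit Cox7c (-0.97 ± 0.14 SE) fell. Of the intercalated cell genes, 1 of 18 rose and 12 fell, 1 up and 12 down adjusted over the list alone (adjusted p = 1.7e-22). These included Rhcg (down 3.13-fold, log2 fold change -1.65 ± 0.08 SE, adjusted p = 1.1e-10), the related Rhbg (down 2.84-fold) and Slc26a4 (down 2.40-fold). Of the distal convoluted tubule genes, 2 of 15 rose and 9 fell, 2 up and 10 down adjusted over the list alone (adjusted p = 8.1e-09, and adjusted p = 0.022 with an estimated correlation). Called members included the protease Klk1 (log2 fold change -0.66 ± 0.06 SE) and Klhl3 (-0.62 ± 0.08 SE). Of the NRF2 targets, 7 of 16 fell, 3 up and 9 down adjusted over the list alone (adjusted p = 0.0026, and adjusted p = 0.011 with an estimated correlation). Of the red blood cell genes, 2 of 3 fell, 2 down adjusted over the list alone (adjusted p = 0.014), among them Slc4a1 (log2 fold change -1.25 ± 0.17 SE), which intercalated cells also express. The next lists of this paragraph passed with the preset correlation only. In the proximal tubule list, which was lower, 5 of 31 rose and 10 fell, 5 up and 12 down adjusted over the list alone (adjusted p = 7.8e-04, and adjusted p = 0.15 with an estimated correlation). The phosphate transporter Slc34a3 fell 2.42-fold (log2 fold change -1.27 ± 0.11 SE, adjusted p = 1.2e-07), the glucose transporter Slc5a2 1.68-fold and the dihydropyrimidinase Dpys 3.15-fold. In the tricarboxylic acid cycle list, which was lower, 5 of 21 fell, 8 down adjusted over the list alone (adjusted p = 0.0015, and adjusted p = 0.15 with an estimated correlation). In the collecting duct principal cell list, which was lower, 3 of 15 rose and 6 fell, 3 up and 6 down adjusted over the list alone (adjusted p = 0.046, and adjusted p = 0.21 with an estimated correlation). The steroid-inactivating Hsd11b2 (log2 fold change -0.90 ± 0.08 SE) and the water channel Aqp3 (-0.83 ± 0.08 SE) fell. The stanniocalcin gene Stc1 (log2 fold change 1.93 ± 0.13 SE) rose. The collecting duct principal cell call ended without wild-type replicates 1, 2 or 4, double mutant replicate 3 or Pbrm1 mutant replicates 1, 2, 3 or 4 (adjusted p from 0.051 to 0.078).

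Of the macrophage markers in double mutants, 13 of 19 rose, 14 up adjusted over the list alone (adjusted p = 2.2e-25). Called genes included the lipopolysaccharide co-receptor Cd14 (log2 fold change 1.45 ± 0.15 SE, adjusted p = 1.2e-06) and Ctss (log2 fold change 1.21 ± 0.10 SE). Of the endothelial markers, 7 of 17 rose, 10 up adjusted over the list alone (adjusted p = 2.8e-05, and adjusted p = 0.022 with an estimated correlation). Those that follow here passed with the preset correlation only. In the extracellular matrix list, which was higher, 16 of 26 rose, 16 up adjusted over the list alone (adjusted p = 1.9e-12, and adjusted p = 0.053 with an estimated correlation). In the lymphocyte list, which was higher, 4 of 17 rose, 4 up and 1 down adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.12 with an estimated correlation). In the ATF4 target list, which was higher, 4 of 19 rose and 1 fell, 8 up and 1 down adjusted over the list alone (adjusted p = 0.041, and adjusted p = 0.16 with an estimated correlation). The ATF4 target call ended without wild-type replicate 2 or double mutant replicate 1 (adjusted p from 0.07 to 0.096). The adipose list median of double mutant replicate 3 was 0.48.

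In double mutants 1473 genes rose and 1233 fell against wild type, 2706 of 22180, and 796 of them changed at least 1.5-fold. Centring gave 1236 higher and 1404 lower genes, and quantile normalization applied again 1436 and 1431 (54.4% higher in the full count, 59.4% for averaged arrays and 69.5% for the 1.5-fold minimum). The probe set for Serpina1d, one of several near-identical alpha-1-antitrypsin genes, fell from 9.73 ± 0.34 to 2.97 ± 0.23 (mean ± SD, log2, n = 4), which lies below the lower quartile of each array. The copy Serpina1c also fell below it, to a mean of 3.02, as did the ribosomal protein gene Rps13, whose transcript has many processed copies in the genome, to 2.42; probe sets of such families may not tell members apart. Cpn1 fell 5.84-fold, Ces1g 4.64-fold and the proton-potassium pump Atp4a 4.53-fold. Rises included Serpina10, an inhibitor of clotting proteases (8.63-fold), Igkv9-120 (to 7.13) and Angptl7 (8.28-fold). The count was 1236 without double mutant replicates 1 to 3, 1724 without wild-type replicates 1 and 2 and 1729 with arrays averaged per description number.

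**Figure D2:**
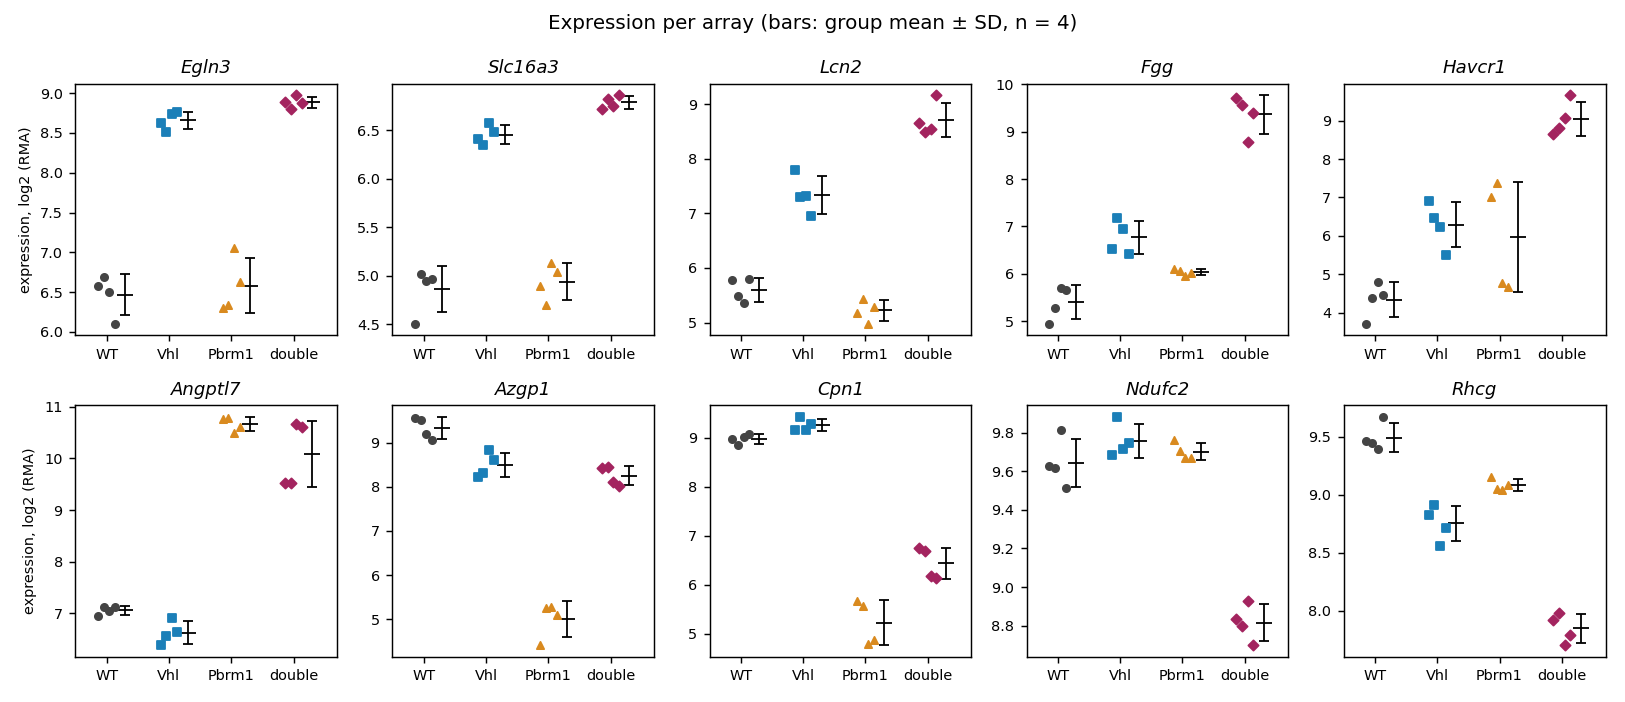
Expression of 10 named genes in each of the 16 arrays (y axes, log2 values after robust multi-array averaging; points, arrays by genotype; bars, group mean ± SD, n = 4). Egln3 and Slc16a3 are higher in Vhl and double mutants, Lcn2, Fgg and Havcr1 are highest in double mutants, and Azgp1 is lowest in Pbrm1 mutants at 5.0 ± 0.41.

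Comparing double with Vhl mutants asked what Pbrm1 loss added. Strain labels match, yet 6 of 19 strain-variable genes were called, and a Vhl mutant batch is possible. Fgg rose 6.04-fold (log2 fold change 2.59 ± 0.20 SE, adjusted p = 5.6e-08, n = 4 arrays per group), Lcn2 2.63-fold (log2 fold change 1.39 ± 0.17 SE, adjusted p = 2.2e-05) and Havcr1 6.88-fold (log2 fold change 2.78 ± 0.48 SE, adjusted p = 8.1e-04). Of the STAT3 targets and acute phase genes, 13 of 22 rose, 17 up adjusted over the list alone (adjusted p = 1.3e-23). Of the tubular injury genes, 12 of 20 rose, 13 up adjusted over the list alone (adjusted p = 1.9e-12). These included Cdkn1a (log2 fold change 0.79 ± 0.12 SE) and the chaperone clusterin, Clu (0.69 ± 0.11 SE). Of the glycolysis genes, 6 of 15 rose, 7 up adjusted over the list alone (adjusted p = 2.9e-04). Car9, a carbonic anhydrase and hypoxia-inducible factor target, rose 3.17-fold (log2 fold change 1.66 ± 0.14 SE, adjusted p = 1.3e-07) and Plin2 fell 2.18-fold (log2 fold change -1.12 ± 0.08 SE, adjusted p = 1.2e-08). The hypoxia list as a whole was higher (3 of 32 rose and 1 fell, 4 up and 1 down adjusted over the list alone, adjusted p = 0.036), a call that ended without double mutant replicate 1 or Vhl mutant replicate 2 (adjusted p from 0.062 to 0.074).

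In double against Vhl mutants, of the oxidative phosphorylation genes 20 of 66 fell, 1 up and 26 down adjusted over the list alone (list median log2 fold change -0.17, adjusted p = 5.1e-14, and adjusted p = 0.0046 with an estimated correlation). Called members included Ndufc2 (log2 fold change -0.95 ± 0.07 SE, adjusted p = 2.6e-08) and the cytochrome oxidase subunits Cox4i1 (log2 fold change -0.37 ± 0.06 SE) and Cox5a (-0.35 ± 0.06 SE). Of the interferon response genes, 8 of 20 fell, 10 down adjusted over the list alone (adjusted p = 6.7e-11). Called genes included the antiviral Rsad2 (log2 fold change -0.73 ± 0.08 SE, adjusted p = 3.4e-06), Usp18 (log2 fold change -0.73 ± 0.11 SE) and the membrane tether Bst2 (-1.49 ± 0.23 SE). Of the intercalated cell genes, 1 of 18 rose and 7 fell, 1 up and 8 down adjusted over the list alone (adjusted p = 1.3e-05, and adjusted p = 0.033 with an estimated correlation). Rhcg fell 1.88-fold, while Foxi1, the transcription factor of these cells, rose 1.4-fold. Of the collecting duct principal cell genes, 1 of 15 rose and 4 fell, 2 up and 7 down adjusted over the list alone (adjusted p = 0.002, and adjusted p = 0.045 with an estimated correlation). The next lists of this paragraph passed with the preset correlation only. In the distal convoluted tubule list, which was lower, 2 of 15 rose and 7 fell, 3 up and 8 down adjusted over the list alone (adjusted p = 1.7e-04, and adjusted p = 0.15 with an estimated correlation). The calcium-binding proteins S100g (log2 fold change -1.38 ± 0.21 SE) and Calb1 (-0.89 ± 0.15 SE) fell. In the proximal tubule list, which was lower, 4 of 31 rose and 6 fell, 4 up and 10 down adjusted over the list alone (adjusted p = 3.8e-04, and adjusted p = 0.12 with an estimated correlation). Dpys (log2 fold change -1.80 ± 0.24 SE), Slc34a3 (-1.02 ± 0.11 SE) and Slc5a2 (-0.57 ± 0.06 SE) fell. In the fatty acid oxidation list, which was lower, 7 of 26 fell, 7 down adjusted over the list alone (adjusted p = 0.002, and adjusted p = 0.12 with an estimated correlation). Acaa2 (log2 fold change -0.41 ± 0.09 SE) and Cyp4a14 (-2.15 ± 0.32 SE) fell. In the tricarboxylic acid cycle list, which was lower, 2 of 21 fell, 2 down adjusted over the list alone (adjusted p = 0.0079, and adjusted p = 0.23 with an estimated correlation). In the cell cycle list, which was lower, 3 of 27 fell, 5 down adjusted over the list alone (adjusted p = 0.0073, and adjusted p = 0.051 with an estimated correlation). In the thick ascending limb list, which was higher, 5 of 16 rose and 1 fell, 7 up and 3 down adjusted over the list alone (adjusted p = 0.027, and adjusted p = 0.32 with an estimated correlation). The tight junction genes Cldn16 (log2 fold change 1.16 ± 0.15 SE) and Cldn19 (0.65 ± 0.14 SE) rose. The thick ascending limb call ended without double mutant replicates 1 or 4 or Vhl mutant replicate 2 (adjusted p from 0.0501 to 0.1). In the NRF2 target list, which was lower, 4 of 16 fell, 6 down adjusted over the list alone (adjusted p = 0.029, and adjusted p = 0.066 with an estimated correlation). The NRF2 target call ended without double mutant replicate 4 or Vhl mutant replicate 3 (adjusted p from 0.065 to 0.071). In the SWI/SNF subunit list, which was higher, 2 of 23 rose, 2 up adjusted over the list alone (adjusted p = 0.034, and adjusted p = 0.21 with an estimated correlation). The SWI/SNF subunit call ended without double mutant replicate 1 or Vhl mutant replicates 1 or 3 (adjusted p from 0.054 to 0.079). In the sex-dependent kidney gene list, which was higher, 4 of 13 rose and 3 fell, 5 up and 3 down adjusted over the list alone (adjusted p = 0.043, and adjusted p = 0.082 with an estimated correlation). The sex-dependent kidney gene call ended without wild-type replicates 1, 2 or 3, double mutant replicates 3 or 4 or Vhl mutant replicate 3 (adjusted p from 0.051 to 0.14).

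Of 22180 genes, 842 rose and 566 fell in double against Vhl mutants, 1408 in all, and 408 changed at least 1.5-fold. The largest changes included Angptl7 (rose 11.2-fold; log2 fold change 3.48 ± 0.21 SE, adjusted p = 2.6e-09), Cyp4a12a (7.93-fold), the corticosteroid carrier Serpina6 (6.43-fold) and the complement gene C4b (5.90-fold), and among falls Gm3893 (8.12-fold), Cpn1 (7.11-fold) and Trim12a (4.72-fold), which the list of strain-variable genes also holds. Serpina1d, Serpina1c and Rps13 fell below the lower quartile. The count was 493 without double mutant replicates 1 to 3, 710 with arrays averaged per description number and 830 without the 3 arrays of raised adipose markers. Quantile normalization applied again gave 719 higher and 779 lower genes, 48.0% higher against 59.8%.

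The comparison of double with Pbrm1 mutants asked what loss of Vhl added in Pbrm1 mutant kidneys. Lcn2 rose 11.4-fold (log2 fold change 3.51 ± 0.17 SE, adjusted p = 5.2e-11, n = 4 arrays per group), Fgg 10.04-fold (log2 fold change 3.33 ± 0.20 SE, adjusted p = 7.4e-10) and Egln3 4.93-fold (log2 fold change 2.30 ± 0.14 SE, adjusted p = 7.4e-10). Of the hypoxia-inducible factor targets, 20 of 32 rose and 1 fell, 20 up and 1 down adjusted over the list alone (adjusted p = 1.1e-28). Of the glycolysis genes, 12 of 15 rose, 12 up adjusted over the list alone (adjusted p = 6.7e-47). These included Pfkp (up 3.93-fold) and Slc16a3 (up 3.61-fold). Of the STAT3 targets, 19 of 22 rose, 19 up adjusted over the list alone (adjusted p = 5.4e-52). Of the tubular injury genes, 17 of 20 rose, 19 up adjusted over the list alone (adjusted p = 6.7e-54). Called members included Vcam1 (up 3.43-fold) and Cdkn1a (up 3.11-fold). Havcr1 rose 8.62-fold (log2 fold change 3.11 ± 0.48 SE, adjusted p = 1.3e-04); its level was uneven among Pbrm1 mutants, at 5.96 ± 1.43 (mean ± SD, log2).

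Macrophage markers were higher (15 of 19 rose, 17 up adjusted over the list alone, adjusted p = 1.1e-30). Called genes included Ctss (log2 fold change 1.48 ± 0.10 SE, adjusted p = 4.5e-09) and the Fc receptor subunit Fcer1g (log2 fold change 1.34 ± 0.13 SE). In the endothelial list, which was higher, 12 of 17 rose, 15 up adjusted over the list alone (adjusted p = 5.8e-13). In the extracellular matrix list, which was higher, 17 of 26 rose and 1 fell, 21 up and 1 down adjusted over the list alone (adjusted p = 3.3e-25, and adjusted p = 0.0027 with an estimated correlation). Fn1 (log2 fold change 1.80 ± 0.12 SE) and Tgfbi (1.29 ± 0.14 SE) rose. Of the oxidative phosphorylation genes, 13 of 66 fell, 28 down adjusted over the list alone (list median log2 fold change -0.15, adjusted p = 1.0e-10, and adjusted p = 0.017 with an estimated correlation). These included Ndufc2 (log2 fold change -0.89 ± 0.07 SE, adjusted p = 2.5e-08) and the cytochrome bc1 subunit Uqcrb (log2 fold change -0.40 ± 0.07 SE). Of the intercalated cell genes, 11 of 18 fell, 11 down adjusted over the list alone (adjusted p = 2.9e-15). Called members included Rhcg (down 2.36-fold). Of the proximal tubule genes, 3 of 31 rose and 11 fell, 4 up and 14 down adjusted over the list alone (adjusted p = 2.7e-06, and adjusted p = 0.035 with an estimated correlation). Of the collecting duct principal cell genes, 1 of 15 rose and 7 fell, 2 up and 8 down adjusted over the list alone (adjusted p = 0.002, and adjusted p = 0.045 with an estimated correlation). The potassium channel subunit Kcne1 fell 2.45-fold and Stc1 rose 6.04-fold. Those that follow here passed with the preset correlation only. In the ATF4 target list, which was higher, 6 of 19 rose, 6 up adjusted over the list alone (adjusted p = 0.0059, and adjusted p = 0.051 with an estimated correlation). In the interferon response list, which was higher, 4 of 20 rose, 7 up and 1 down adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.19 with an estimated correlation). In the smooth muscle and renin cell list, which was higher, 4 of 9 rose, 5 up adjusted over the list alone (adjusted p = 5.9e-05, and adjusted p = 0.055 with an estimated correlation). In the distal convoluted tubule list, which was lower, 1 of 15 rose and 5 fell, 1 up and 5 down adjusted over the list alone (adjusted p = 0.002, and adjusted p = 0.23 with an estimated correlation). In the tricarboxylic acid cycle list, which was lower, 2 of 21 fell, 7 down adjusted over the list alone (adjusted p = 0.0015, and adjusted p = 0.15 with an estimated correlation).

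In double against Pbrm1 mutants 1513 genes rose and 747 fell, 2260 in all, and 748 changed at least 1.5-fold. Rises included Serpina10 (9.49-fold), Azgp1 (9.48-fold; log2 fold change 3.24 ± 0.18 SE, adjusted p = 2.8e-10) and Serpina6 (7.17-fold), and falls Akr1c18 (4.69-fold) and Trim12a (3.54-fold). Serpina1d, Serpina1c, Rps13 and the vomeronasal receptor gene Vmn1r20 (mean 3.40) fell below the lower quartile. The count was 1034 without double mutant replicates 1 to 3, 1329 without Pbrm1 mutant replicates 3 and 4 and 1398 with arrays averaged per description number. Centring gave 1193 higher and 1079 lower genes (52.5% higher against 66.9%), and quantile normalization applied again 1339 and 1059 (55.8% higher), but 72.7% for averaged arrays and 80.1% for the 1.5-fold minimum.

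The single mutants were compared directly. In Vhl against Pbrm1 mutants Cpn1 was 16.4-fold higher (log2 fold change 4.03 ± 0.17 SE, adjusted p = 1.7e-11, n = 4 arrays per group), Azgp1 11.3-fold higher (log2 fold change 3.50 ± 0.18 SE, adjusted p = 1.2e-10) and Angptl7 16.5-fold lower (log2 fold change -4.05 ± 0.21 SE, adjusted p = 1.4e-10). Egln3 was 4.21-fold and Lcn2 4.34-fold higher in Vhl mutants. Of the hypoxia-inducible factor targets in Vhl relative to Pbrm1 mutants, 17 of 32 rose and 2 fell, 18 up and 2 down adjusted over the list alone (adjusted p = 5.1e-25). Of the glycolysis genes, 9 of 15 rose, 10 up adjusted over the list alone (adjusted p = 5.4e-36). Called genes included the pyruvate kinase Pkm (log2 fold change 0.94 ± 0.07 SE) and Slc16a3 (1.52 ± 0.12 SE). Of the interferon response genes, 13 of 20 rose, 17 up adjusted over the list alone (adjusted p = 1.1e-21). These included Oasl2 (log2 fold change 1.17 ± 0.12 SE, adjusted p = 2.2e-06) and Ifit1 (log2 fold change 1.04 ± 0.13 SE).

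Markers of immune, vascular and matrix cells were higher in Vhl than in Pbrm1 mutants. In the macrophage list, which was higher, 18 of 19 rose, 18 up adjusted over the list alone (adjusted p = 1.1e-30). The complement subunit C1qb (log2 fold change 1.27 ± 0.14 SE) rose. In the endothelial list, which was higher, 15 of 17 rose, 16 up adjusted over the list alone (adjusted p = 4.0e-24). Pecam1 (log2 fold change 0.67 ± 0.07 SE) and the growth factor receptor Kdr (0.61 ± 0.08 SE) rose. In the extracellular matrix list, which was higher, 18 of 26 rose and 1 fell, 22 up and 1 down adjusted over the list alone (adjusted p = 1.9e-26, and adjusted p = 0.0019 with an estimated correlation). In the smooth muscle and renin cell list, which was higher, 5 of 9 rose, 7 up adjusted over the list alone (adjusted p = 1.8e-09, and adjusted p = 0.0031 with an estimated correlation). In the lymphocyte list, which was higher, 3 of 17 rose, 4 up adjusted over the list alone (adjusted p = 0.0015, and adjusted p = 0.036 with an estimated correlation). Of the tubular injury genes, 12 of 20 rose, 13 up adjusted over the list alone (adjusted p = 3.7e-26). Of the STAT3 targets, 9 of 22 rose, 13 up adjusted over the list alone (adjusted p = 2.1e-13). Called members included Osmr (1.3 ± 0.10 SE). Of the cell cycle genes, 5 of 27 rose, 8 up adjusted over the list alone (adjusted p = 1.0e-06). Of the intercalated cell genes, 8 of 18 fell, 1 up and 10 down adjusted over the list alone (adjusted p = 1.3e-05, and adjusted p = 0.033 with an estimated correlation). Of the sex-dependent kidney genes, 1 of 13 rose and 7 fell, 2 up and 7 down adjusted over the list alone (adjusted p = 1.2e-04, and adjusted p = 5.6e-04 with an estimated correlation). Cyp4a12a was 12.3-fold lower and Cyp4a14 10.1-fold higher in Vhl mutants. Those that follow here passed with the preset correlation only. In the thick ascending limb list, which was lower, 4 of 16 fell, 6 down adjusted over the list alone (adjusted p = 3.4e-04, and adjusted p = 0.099 with an estimated correlation). In the SWI/SNF subunit list, which was lower, 1 of 23 fell, 0 down adjusted over the list alone (adjusted p = 0.043, and adjusted p = 0.23 with an estimated correlation). The SWI/SNF subunit call ended without Pbrm1 mutant replicates 1, 2 or 3 or Vhl mutant replicates 1 or 3 (adjusted p from 0.054 to 0.09).

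In Vhl against Pbrm1 mutants 1045 genes were higher and 611 lower, 1656 in all, and 562 changed at least 1.5-fold. Further large differences were those of Gm3893 (7.64-fold higher), Cyp2c23 (6.33-fold higher) and 2610507I01Rik (4.95-fold higher), and of Akr1c18 (5.47-fold lower), Eddm3b (4.47-fold lower), the glucuronosyltransferase Ugt2a3 (log2 mean 3.18 against 5.43) and the neuropeptide Y receptor gene Npy6r (3.63 against 5.69). The count was 923 without Pbrm1 mutant replicates 3 and 4 and 916 with arrays averaged per description number. Centring gave 788 higher and 1017 lower genes, 43.7% higher against 63.1%, but 74.1% for averaged arrays and 77.4% for the 1.5-fold minimum.

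The interaction asked whether loss of both genes changed expression by more or less than the sum of the single losses on the log2 scale. Acute phase and injury genes exceeded that sum: Fgg by a log2 value of 1.96 ± 0.28 SE (limma adjusted p = 5.6e-04, n = 4 arrays per group), Lcn2 by 1.78 ± 0.24 SE (adjusted p = 2.8e-04), Fga by 1.32 ± 0.18 SE (adjusted p = 2.7e-04) and the transcription factor gene Stat3 itself by 0.59 ± 0.09 SE (adjusted p = 0.0011). Of the STAT3 targets and acute phase genes, 8 of 22 lay above the sum (14 adjusted over the list alone, adjusted p = 9.3e-17). Of the tubular injury genes, 9 of 20 lay above it (12 adjusted over the list alone, adjusted p = 1.6e-16). Called genes included clusterin, Clu (0.95 ± 0.15 SE), and the receptor of the cytokine TWEAK, Tnfrsf12a (1.09 ± 0.21 SE). Azgp1 lay 17.0-fold above the sum (4.09 ± 0.25 SE, adjusted p = 6.0e-09): it measured 9.35 ± 0.25 in wild type, 5.0 ± 0.41 in Pbrm1 mutants and 8.26 ± 0.22 in double mutants (mean ± SD, log2).

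Lists of metabolism and of tubule cells passed as well. In the glycolysis list, which was above the sum, 2 of 15 passed above it, 4 above adjusted over the list alone (adjusted p = 6.0e-04). In the hypoxia list, which was above the sum, 1 of 32 passed above it and 1 below, 3 above and 1 below adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.0073 with an estimated correlation). Pfkp lay above the sum (0.77 ± 0.10 SE) and Plin2 below it (-0.86 ± 0.11 SE). The collecting duct principal cell list lay below it (1 of 15 passed above it and 3 below, 1 above and 6 below adjusted over the list alone, adjusted p = 2.9e-04, and adjusted p = 0.017 with an estimated correlation). These included Tmem45b (-1.0 ± 0.13 SE) below and Stc1 (0.98 ± 0.19 SE) above. The list of Pbrm1 neighbours lay above it (2 of 31 passed above it, 7 above adjusted over the list alone, adjusted p = 1.6e-04), as did its 24 members on chromosome 14 (2 above, 5 adjusted over the list alone, adjusted p = 0.0031). Those that follow here passed with the preset correlation only. The oxidative phosphorylation list median was -0.11. In the oxidative phosphorylation list, which was below the sum, 4 of 66 passed below it, 6 below adjusted over the list alone (adjusted p = 6.7e-07, and adjusted p = 0.069 with an estimated correlation). Ndufc2 (-1.01 ± 0.10 SE) and Uqcrb (-0.68 ± 0.10 SE) lay below the sum. In the proximal tubule list, which was below the sum, 2 of 31 passed above it and 6 below, 2 above and 11 below adjusted over the list alone (adjusted p = 2.7e-05, and adjusted p = 0.06 with an estimated correlation). Slc34a3 (-0.83 ± 0.16 SE) lay below the sum. In the thick ascending limb list, which was above the sum, 1 of 16 passed above it, 8 above and 1 below adjusted over the list alone (adjusted p = 0.0094, and adjusted p = 0.23 with an estimated correlation). In the extracellular matrix list, which was above the sum, 2 of 26 passed above it, 5 above and 1 below adjusted over the list alone (adjusted p = 1.5e-04, and adjusted p = 0.32 with an estimated correlation). Fn1 (1.0 ± 0.16 SE) lay above the sum. In the interferon response list, which was below the sum, 1 of 20 passed below it, 2 below adjusted over the list alone (adjusted p = 0.034, and adjusted p = 0.25 with an estimated correlation). The interferon response call ended without wild-type replicates 3 or 4, double mutant replicate 3, Pbrm1 mutant replicates 1 or 3 or Vhl mutant replicate 1 (adjusted p from 0.051 to 0.099). In the SWI/SNF subunit list, which was above the sum, no member of 23 passed, 1 above adjusted over the list alone (adjusted p = 0.036, and adjusted p = 0.22 with an estimated correlation). The SWI/SNF subunit call ended without wild-type replicates 1 or 2, double mutant replicates 1 or 3, Pbrm1 mutant replicate 4 or Vhl mutant replicates 1 or 3 (adjusted p from 0.051 to 0.075). In the tricarboxylic acid cycle list, which was below the sum, no member of 21 passed (adjusted p = 0.034, and adjusted p = 0.35 with an estimated correlation). The tricarboxylic acid cycle call ended without wild-type replicate 4, double mutant replicate 4 or Vhl mutant replicates 2 or 4 (adjusted p from 0.069 to 0.099). In the fatty acid oxidation list, which was below the sum, 1 of 26 passed below it, 1 below adjusted over the list alone (adjusted p = 0.014, and adjusted p = 0.22 with an estimated correlation). The fatty acid oxidation call ended without Vhl mutant replicate 2 (adjusted p = 0.057).

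The interaction passed for 583 genes, 394 above and 189 below the sum, and 340 of them by at least 1.5-fold. The largest values above it also held Serpina6 (5.88-fold), C4b (5.37-fold), the fifth complement component Hc (log2 mean 6.10 in double mutants and 3.68 in wild type), Serpina10 (5.04-fold) and Hspa1a (6.71-fold), whose call ended without wild-type replicates 1 or 2, double mutant replicates 1 or 2, Pbrm1 mutant replicates 3 or 4 or Vhl mutant replicates 1, 2 or 3 (adjusted p from 0.056 to 0.071). Values below it included 9030619P08Rik (5.62-fold), Trim12a (4.87-fold) and, given no fold, Serpina1d, Serpina1c, Rps13 and Vmn1r20. The strain difference between wild type and mutants enters the interaction once, with a minus sign, and the count was 374 without wild-type replicate 2, 210 without wild-type replicates 1 and 2, 246 without double mutant replicates 1 to 3, 261 without Pbrm1 mutant replicates 3 and 4, 99 with arrays averaged per description number and 303 without the 3 arrays of raised adipose markers. It was 884 with no block and 337 without a trend in the prior variance, and quantile normalization applied again gave 296 higher and 275 lower genes, 51.8% higher against 67.6%.

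**Figure D3:**
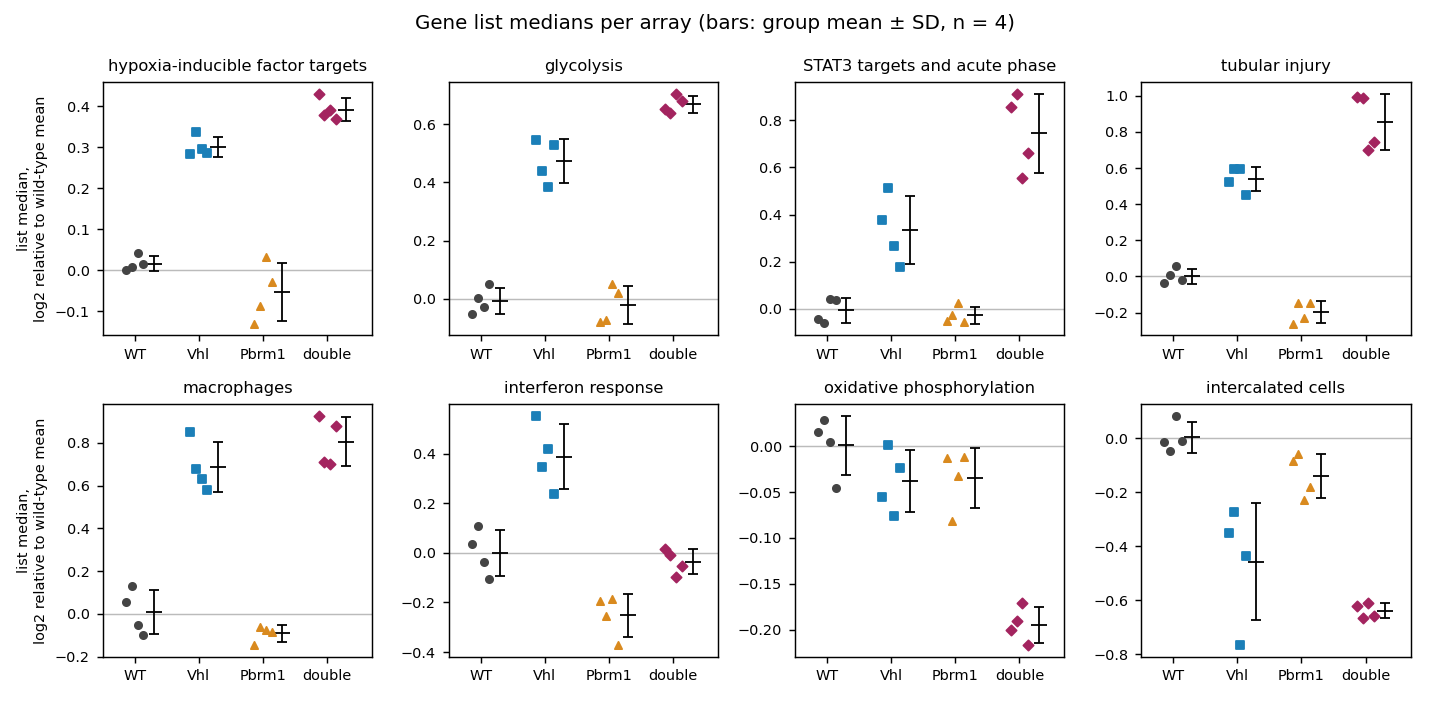
Median of 8 fixed gene lists in each array (y axes, log2 relative to the wild-type mean of each gene; points, arrays by genotype; bars, group mean ± SD, n = 4). The macrophage medians lie between 0.58 and 0.85 in Vhl mutants and between -0.10 and 0.13 in wild type, and the oxidative phosphorylation medians are lowest in the double mutants.

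The overlap of the comparisons with wild type was counted with the shared wild-type arrays in mind. Vhl and double mutants both rose for 335 genes and both fell for 220, with 4 changed in opposite directions; independent lists of the same sizes would share 30.1 and 22.1. Pbrm1 and double mutants shared 176 rises and 251 falls, with 61 opposite (independent lists 23.4 and 30.2). The single mutants shared 44 rises and 82 falls, with 43 opposite (independent lists 7.19 and 9.74). Unchanged groups simulated against the same controls shared 0 calls in every pair and so do not show what shared controls add to these overlaps. With the controls split, 2 arrays to each comparison, the first pair shared 188 rises and 86 falls in one arrangement and 168 and 65 in the other. The second pair shared 90 and 100, or 86 and 97, and the single mutants 14 and 22, or 14 and 18. Across all genes, which are not independent replicates, the log2 fold changes of Vhl and double mutants correlated with r = 0.556 (simulated 0.494), those of Pbrm1 and double mutants with r = 0.413 (simulated 0.494) and those of the single mutants with r = 0.314 (simulated 0.495). The last 2 lie below the simulated values. The covariances exceeded the simulated ones by 0.0227, 0.0152 and 0.00439: they were 0.0311 against 0.00842, 0.0236 against 0.00841 and 0.0127 against 0.00835. With split controls the correlations were 0.235 and 0.39, 0.151 and 0.235, and 0.0149 and 0.0725 in the same order.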

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

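In a group of 4 arrays, a value was singled out when its gap to the nearest other, as a share of the group's range, exceeded Dixon's critical value. Of 488 groups of named genes 26 met this, and of 128 groups of list medians 3; chance gives about 1 in 20. High log2 values among wild-type arrays were those of Emcn in replicate 3 (9.06, others 8.78 to 8.81), Stc1 in replicate 1 (6.11, others 5.87 to 5.89) and Tnnc1 in replicate 1 (7.93, others 7.14 to 7.16). Low log2 values among wild-type arrays were those of Cx3cr1 in replicate 2 (5.96, others 6.15 to 6.18), Slc16a3 in replicate 1 (4.50, others 4.94 to 5.02) and Trim12a in replicate 3 (5.42, others 5.91 to 6.00). High log2 values among Vhl mutant arrays were those of 2610507I01Rik in replicate 4 (7.15, others 6.93 to 6.94), Emcn in replicate 4 (9.58, others 9.38 to 9.39), Kcne1 in replicate 2 (6.46, others 5.96 to 6.03), Mki67 in replicate 4 (6.65, others 6.30 to 6.34) and Rps13 in replicate 2 (5.55, others 5.12 to 5.18). Low log2 values among Vhl mutant arrays were those of Bst2 in replicate 4 (5.81, others 6.15 to 6.19), Cox5a in replicate 1 (9.76, others 9.95 to 9.96) and Hc in replicate 3 (3.69, others 3.83 to 3.85). High log2 values among Pbrm1 mutant arrays were those of Eddm3b in replicate 2 (6.45, others 6.12 to 6.15), Ifit1 in replicate 1 (5.87, others 5.36 to 5.43) and Slc2a1 in replicate 2 (8.78, others 8.54 to 8.56). Low log2 values among Pbrm1 mutant arrays were those of C1qb in replicate 4 (6.58, others 6.89 to 6.92), Gbp2b in replicate 2 (3.99, others 5.02 to 5.22), Npy6r in replicate 1 (5.59, others 5.71 to 5.73) and S100g in replicate 3 (10.79, others 11.03 to 11.07). High log2 values among double mutant arrays were those of Cdkn1a in replicate 1 (8.82, others 8.55 to 8.59) and Rgs5 in replicate 1 (9.57, others 9.24 to 9.29). Low log2 values among double mutant arrays were those of Cox4i1 in replicate 4 (9.74, others 9.88 to 9.91), Krt18 in replicate 3 (6.86, others 7.20 to 7.23) and Pkm in replicate 3 (10.42, others 10.63 to 10.67). Among list medians (log2, relative to the wild-type mean), high values were those of ATF4 targets in Vhl mutant replicate 1 (0.165, others 0.033 to 0.045) and of adipose tissue in Pbrm1 mutant replicate 3 (0.653, others -0.073 to 0.014) and of red blood cells in wild-type replicate 3 (0.047, others -0.033 to -0.028).

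By the test of the interaction, 583 genes and, with the preset and the estimated correlation, 6 lists departed from the sum of the single effects. Strain differences also enter here, those among the mutant groups included. The list medians of the interaction (log2) were 0.54 for STAT3 targets and acute phase genes, 0.59 for tubular injury, 0.17 for hypoxia-inducible factor targets, 0.14 for glycolysis, -0.23 for collecting duct principal cells and 0.18 for the list of Pbrm1 neighbours, which holds 31 genes, 24 on its chromosome.

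The 17824 probe sets without a single gene symbol were outside the comparisons. In the same limma fit, adjusted among themselves, 27 of them were called in Vhl mutants, 200 in Pbrm1 mutants and 485 in double mutants against wild type. The annotation used here gives them no single gene.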

How the results depend on the processing

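The tests without the 3 arrays of raised adipose markers, those of the Pbrm1 neighbours on chromosome 14 and those of named genes with arrays or numbers left out, were chosen only after the data were seen. Counts of called genes follow in the order Vhl, Pbrm1 and double mutants against wild type, double against Vhl and against Pbrm1 mutants, Vhl against Pbrm1 mutants, and the interaction. They were 851, 895, 2706, 1408, 2260, 1656, 583 as reported, 246, 274, 1729, 710, 1398, 916 and 99 with arrays averaged per description number, 262, 235, 796, 408, 748, 562 and 340 with a change of at least 1.5-fold as well, and 564, 501, 2023, 830, 1576, 1133 and 303 without the 3 arrays of raised adipose markers. The interaction count was 884 with no block and 337 without a trend. Leaving out each array or each description number in turn gave 275 to 895 (Vhl mutant against wild type), 318 to 995 (Pbrm1 mutant against wild type), 1236 to 2844 (double mutant against wild type), 493 to 1462 (double against Vhl mutant), 1034 to 2382 (double against Pbrm1 mutant), 923 to 1735 (Vhl against Pbrm1 mutant), 210 to 755 (the interaction), and single arrays alone 537 to 895, 605 to 957, 2016 to 2803, 1070 to 1449, 1781 to 2318, 1292 to 1735, 374 to 695 in the same order. Single arrays moved 2 counts by over 1.5 times: 537 without wild-type replicate 1, 559 without wild-type replicate 2, 541 without Vhl mutant replicate 3 for Vhl mutants against wild type, and 374 without wild-type replicate 2 for the interaction. Without double mutant replicates 1 to 3 that group is a lone array, assumed to vary like the other groups. Averaging and leaving out arrays leave fewer samples; the cause of the other moves was not tested. The other alternatives left these counts within 1.5 times, and the fit to only the groups compared does not apply to the interaction. The replicate block gave 1098, 1062, 3075, 1702, 2552, 1879 and 839. Deviations of the 24 pairs of arrays with the same replicate number correlated between -0.0744 and 0.059, 0 of them over 0.1, and the best match had the same number in 10 of 48 tests, so the numbers do not pair the arrays. No call reversed. The deposited values carry no background signal, so no detection limit was set. Of 251 values of named genes, the deleted genes included, 26 were no longer called with averaged arrays, 23 with the fold minimum, 8 without a trend, 8 without the adipose arrays, 3 with mean probe sets, 1 with only the groups compared (the interaction aside) and 1 with quantile normalization, and summed over the refits 37 calls were lost when each array was left out and 63 when each number was. Of 109 list calls, the estimated correlation ended 42, the filter on dim genes 14, quantile normalization 8, averaging 5, the adipose arrays 4, mean probe sets 2 and centring 1. Summed over the refits, 54 list calls were lost when each array was left out.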

Other observations

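The tests of neighbouring genes, of strain-variable genes, of macrophage markers and of the proximal tubule share, the splits with an estimated correlation, and the gene values of this paragraph were chosen only after the results were seen. Strain-variable genes differed between groups (log2 fold changes, limma). The mitochondrial transhydrogenase gene Nnt was higher than wild type in double mutants (0.58, adjusted p = 1.7e-06) and Pbrm1 mutants (0.32, adjusted p = 0.0046), while the value in Vhl mutants was -0.10, adjusted p = 0.48. Hc, the fifth complement component, rose in double mutants (adjusted p = 5.9e-07) and Trim12a, a tripartite motif gene, fell (-1.78, adjusted p = 7.7e-07); in Vhl and Pbrm1 mutants Hc had adjusted p = 0.87 and adjusted p = 0.99. Ide was lower than wild type in Vhl (-0.54, adjusted p = 9.9e-06), Pbrm1 (-0.42, adjusted p = 8.8e-05) and double mutants (-0.53, adjusted p = 1.0e-06). The protease inhibitor genes Serpina10, Serpina6, Serpina1d and Serpina1c take places 1, 2, 6 and 8 of a cluster on chromosome 12 (GRCm38.p6 order). In double against Pbrm1 mutants the first pair rose (3.25 ± 0.19 and 2.84 ± 0.18 SE) and the second fell (adjusted p = 3.2e-13 and 2.0e-05). Lists of podocytes, adipose tissue, adrenal cortex, sex-linked genes and neighbours of Vhl passed in no comparison, with lowest adjusted p = 0.18, 0.17, 0.18, 0.81 and 0.13. Double mutant replicate 3, whose description repeats that of replicate 2, differed from it with an SD of 0.269 over all genes, against 0.228 from replicate 4 and 0.21 between replicates 1 and 2.

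Called genes changed at least 1.5-fold lay near each other in Pbrm1 mutants against wild type more than in shuffles, which may come from segments inherited with the deleted genes or from the mixed strain. The number with another such gene of a different name stem within 5 places was (median and 99th percentile of 1000 shuffles in parentheses) 48 (30 and 48) in Vhl, 53 (24 and 40) in Pbrm1 and 281 (251 and 289) in double mutants against wild type, 95 (72 and 97) in double against Vhl, 243 (228 and 263) in double against Pbrm1 and 165 (136 and 168) in Vhl against Pbrm1 mutants. The other comparisons lay above the median and not above the 99th percentile, which leaves segments of few called genes open. Of 19 strain-variable genes, 3 (3), 5 (3), 8 (6), 6 (4), 6 (5) and 9 (4) were called in the same order (99th percentile of random lists in parentheses). This goes with strain in all but the first (95th percentile 2, undecided). Whether immune members follow inflammation was not tested. An effect of the deletions on neighbours stays open, untested, and littermate controls would separate it from strain.

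Macrophage markers rose in Vhl (16 of 19) and double mutants (13 of 19). The most abundant, by mean log2, were Csf1r (7.82 in wild type, 7.77 in Vhl and 8.01 in double mutants), C1qb (7.28, 8.10 and 7.40) and Ctss (6.70, 7.68 and 7.91). In wild type 13 lay above the median gene, and 0 were in another list. A lower share of tubule cells would raise podocyte markers alike, but the macrophage minus podocyte list median was 0.64 higher than wild type in Vhl mutants and 0.78 in double mutants (wild-type SD 0.11, exact 2-sided permutation p = 0.0286 for both, the smallest possible, higher in 4 of 4 arrays; over the 2 description numbers per group it would be 0.333). With the adipose list median as a covariate the macrophage differences were 0.67 and 0.84, against 0.68 and 0.80 without it, which argues against fat. Its most abundant markers were Lpl (10.85, 10.41 and 9.98), Car3 (8.51, 8.56 and 8.66) and Fabp4 (8.14, 8.49 and 8.72) in the group order above. The mean median of Pbrm1 mutants was -0.091 (wild type 0.010, SD 0.10), which argues against a background that all mutants share. A batch of the Vhl mutants stays open for their own rise only. More macrophages after loss of Vhl stay open for both, and stained sections would count them.

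The oxidative phosphorylation list fell in double mutants. Its median was -0.17 against wild type, -0.17 against Vhl and -0.15 against Pbrm1 mutants, below the lowest of 10000 random lists of matched expression (-0.13, -0.071 and -0.11), which argues against a trend with expression level. A lower share of mitochondria-rich proximal tubule cells would lower their markers at least as much. Their median was -0.073 (bootstrap -0.18 to -0.017), -0.094 (-0.14 to -0.003) and -0.15 (-0.26 to -0.054) in the same order. Against Vhl mutants the interval lay above the oxidative phosphorylation median, but without a spread between arrays it cannot exclude that share as the sole cause. The share stays open in each of these comparisons. Lower expression within cells stays open, distal cell shares were not tested, and sorted cells would tell these apart.

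Arrays were regrouped in every split into groups of 4. For called genes, only the real of 35 splits gave a count as large in each pairwise comparison. This excludes chance only if the 4 arrays of a group are independent. Interaction splits (1 of 100 sampled as large) also break up the single effects and cannot exclude chance. The real and highest other counts were 851 and 18 for Vhl, 895 and 2 for Pbrm1 and 2706 and 4 for double mutants against wild type. They were 1408 and 39 for double against Vhl, 2260 and 1 for double against Pbrm1, 1656 and 33 for Vhl against Pbrm1 mutants and 583 and 18 for the interaction. For called lists the splits as large were, in the same order (real and highest other in parentheses), 2 of 35 (18 and 18), 1 of 35 (12 and 9), 1 of 35 (17 and 16), 1 of 35 (17 and 15), 8 of 35 (16 and 18), 9 of 35 (15 and 17) and 7 of 100 (14 and 18). Even then chance is not excluded for the list counts of the first and the last 3. Splits that move 1 array per group keep part of the real difference. With an estimated correlation, real and highest other list counts were 14 and 11, 4 and 2, 11 and 7, 8 and 8, 11 and 13, 13 and 13, 6 and 11, and chance is not excluded for the last 4. Splits with 2 arrays of each group on either side then called at most 3 lists, but up to 14 with the preset one. If arrays of a description number come from 1 animal, at most 3 splits keep animals whole. That is too few for a share under 0.05 in any pairwise comparison.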
